A study of Mus musculus with 45 samples.

How the data were processed

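The deposited tables of raw read counts per gene were used for every result. According to the sample labels, polyA RNA was made into TruSeq version 1 libraries and sequenced as paired reads of 40 to 50 bases. Reads were aligned to the mouse genome build mm9 with TopHat 1.4.0 and counted with HTSeq (version not stated) and a refFlat gene model. The deposited signal values are, per the authors' labels and file names, read counts normalized with CQN and DESeq2 1.0.18 before deposit. They were used in one alternative only, on a log2 scale, with limma. Groups were taken from the sample titles and characteristics. No library was left out of the reported fit.

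Genes were kept by filterByExpr with a minimum count of 10, which left 14067 of 23227 genes (3737 had no read in any library). Library sizes were scaled by TMM, all 45 libraries were fitted together in edgeR 4.0.16 with one coefficient per group, and 22 comparisons were tested with the quasi-likelihood F test. P values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at a false discovery rate below 0.05. Fold changes are log2 values of the edgeR fit at its default prior count. The log2 CPM behind list tests, correlations of libraries and principal components had a prior count of 2. CPM are counts scaled to library size by TMM. Lists of genes were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation; these p values were adjusted over all lists of a comparison. Members of a list were also adjusted over the list alone. Of 173 list calls with the preset correlation, 2 held with an estimated correlation: interferon-stimulated genes after 6 weeks of HFD and clock genes after 15 min of insulin on chow. The lists and the rules for genes named in the results were fixed before the data were examined. Named were the largest fold changes without overlap between libraries at a mean of 5 CPM or more, the members of each list with the smallest adjusted p, and 7 genes given in every comparison; some genes that these rules name are not reported here.

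Alternatives were RLE scaling, no filter, a block for the replicate number, a fit of only the groups compared and DESeq2 1.42.0. Further alternatives were the deposited normalized values, leaving out each library of the groups compared, and leaving out replicates 4 to 6 at 30 min. Added after seeing the data were the removal of trends with exon length and GC content, the removal of the basal and the metformin library with the lowest length correlation (replicate 1 of both on 16-week HFD), and combinations with the replicate block. The block was also an added alternative for the gene lists, and the block and the left-out libraries were added for the correlation of diet responses. The libraries of each comparison were also split in all other ways, or in 100 drawn ways where there were more, and, chosen after the results were seen, for metformin by diet in 100 drawn ways that exchanged labels on both HFD diets only within same-numbered pairs. In simulated counts with known changes, 84%, 90% and 92% of genes changed 2-fold were recovered in 3 of the comparisons, with 3.7%, 2.3% and 5.4% of calls false. At 1.5-fold 36%, 56% and 36% were recovered. Each gene had the same spread in all groups of these counts, without length or GC trends or a library that stood apart. The shares of false calls therefore need not hold for the real libraries. Gene positions are those of the deposited mm9 gene models, and shared 40-base words were counted in GENCODE M21 transcripts, which held a transcript for 98.1% of genes. Replicate numbers are shared by the groups, but no label says that a number marks a mouse, litter or day. Same-numbered libraries of basal and metformin groups deviated from their group means together on 16-week HFD (correlations of 0.24, 0.15 and 0.12) and on 6-week HFD (0.41, 0.16 and 0.3), so these numbers were taken as pairs from the data alone. Of 91 pairs of groups, 4 had all 3 correlations over 0.1; the others were chow basal with 6-week HFD metformin (0.29, 0.13 and 0.25) and 120 with 15 min of insulin on 16-week HFD (0.38, 0.22 and 0.57), which no comparison sets directly against each other, so no paired fit was made. Correlations all under -0.1 also occurred, as between 16-week and 6-week HFD metformin (-0.16, -0.16 and -0.13). The median over all same-numbered pairs was -0.01. Pairs found in this way rest on a search of the data, and the fits with the replicate block are given among the alternatives. R 4.3.3 and Python 3.11.15 were used.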

Results

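Liver mRNA from C57BL/6J mice had been sequenced in 45 libraries, and the deposited read counts per gene were analysed. The mice ate chow, a high-fat diet (HFD) for 6 weeks or HFD for 16 weeks, and all were fasted overnight and 24 weeks old when the liver was taken. HFD began at 18 weeks of age in the 6-week groups and at 8 weeks in the 16-week groups. Duration of HFD and age at its start therefore cannot be separated. Basal livers came from all 3 diets. Livers taken 15, 30, 60 or 120 min after insulin came from chow and 16-week HFD mice, and livers after metformin in the drinking water came from all 3 diets. Insulin was given at 1 U/kg and metformin at 270 mg/kg per day. Each of the 14 groups held 3 libraries, except 6 at 30 min of insulin on 16-week HFD. The series design gives at least 3 mice per group, and no label links 2 libraries to one mouse. Depth was 18.2 to 50.3 M counted reads per library. It was 19 to 45.7 M in chow basal, 35.1 to 50.3 M in 6-week HFD basal and 21 to 23.9 M in 16-week HFD basal libraries. Of 23227 genes, 14067 passed the expression filter. Values given below are log2 fold changes ± standard errors, and CPM are counts scaled for library size. The standard error was taken as the absolute fold change divided by the square root of its F statistic. It is approximate where a group has few counts. Changes called the largest are so among called genes with a mean of 5 CPM or more whose libraries did not overlap between the groups compared. The chow basal libraries are the reference for insulin and metformin on chow and for both diets without metformin. Likewise, 16-week HFD basal is the reference for insulin and metformin on that diet. A gene called in several such comparisons is therefore not a separate finding in each.

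Libraries of the metformin groups stood apart by gene length. In all 9 of them the deviation of a gene from its mean level fell with its exon length, with Spearman correlations from -0.61 (16-week HFD metformin replicate 1) to -0.13 (chow metformin replicate 3). The 16-week HFD basal replicate 1 had -0.22. GC content was correlated from 0.19 to 0.22 in replicates 1 to 3 at 30 min of insulin on 16-week HFD and from -0.22 to -0.13 in replicates 4 to 6. It was correlated at -0.08, -0.29 and -0.29 in chow basal, -0.18, -0.23 and -0.15 in 6-week HFD basal and 0.28, 0.32 and 0.17 in 16-week HFD basal replicates 1 to 3, so the basal groups at 16 weeks and on chow differed in this trend. Genes called uncertain below have at least 20% of their 40-base exon words in other genes. The library kit does not keep the strand of a read. Of the genes named below, Bhlhe40, Srebf1, Plk3, Irs2, Txnip, Eng, Stab1, Gnl3, Nop56 and Gt(ROSA)26Sor share exon bases with a gene on the opposite strand. Gm129, Gm6484, Lrat, Tnnt3, Acadvl and E030018B13Rik lie in or over such a gene without shared exon bases. All of these genes are left uncertain by the reads of that neighbour.

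**Figure D1:**
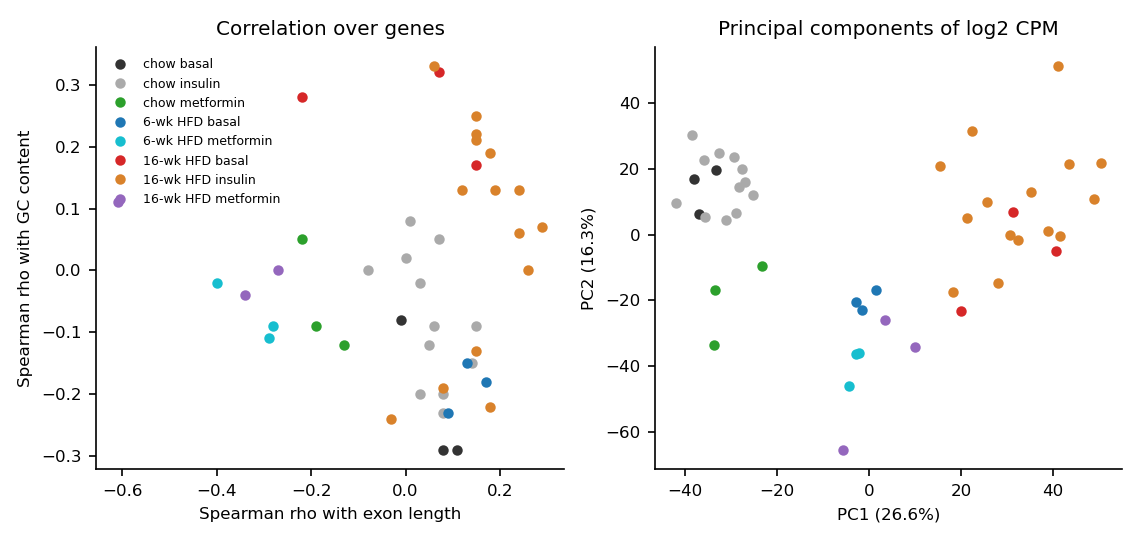
Each point is a library, coloured by treatment; the left panel gives the Spearman correlation of gene deviations with exon length and with GC content, and the right panel gives the first and second principal components (26.6% and 16.3% of variance). The metformin libraries lie at the low end of the length axis, lowest at -0.61.

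After 16 weeks of HFD, basal livers were compared with basal livers on chow. Interferon-stimulated genes were higher, with 26 of 27 called, among them Isg15, a ubiquitin-like antiviral protein (2.40 ± 0.30, adjusted p = 3.51e-07), and Ifit3, uncertain (2.00 ± 0.27). Of 22 genes of fatty acid and triglyceride synthesis, 11 were higher and 3 lower. Dgat2, which makes triglyceride, rose by 1.28 ± 0.13 (adjusted p = 9.57e-09). Thrsp rose by 5.28 ± 0.60 and the lipogenic regulator Srebf1 by 2.17 ± 0.30. Of 30 genes of fatty acid oxidation and ketogenesis, 16 were lower and 1 higher. Cyp4a14, an omega-hydroxylase, was at -2.75 ± 0.26 (adjusted p = 8e-09), Cyp4a10, uncertain, at -1.92 ± 0.22, and the peroxisomal enzyme Ehhadh at -3.06 ± 0.37. Clock genes were 9 higher and 3 lower of 18, with Bhlhe40 at 1.97 ± 0.25, Per3 at 2.34 ± 0.39 and Arntl at -2.15 ± 0.38. The unfolded protein response had 12 of 19 genes higher (Edem1 0.67 ± 0.14, Creld2 1.59 ± 0.38). Acute phase genes had 10 higher and 1 lower of 25 (Saa4 2.91 ± 0.30, Steap4 2.56 ± 0.37). Ribosome biogenesis had 10 lower and 1 higher of 24 (Nop58 -1.05 ± 0.11, Gnl3 -0.70 ± 0.10). Male-biased genes had 10 lower and 1 higher of 15 (Cyp4a12b, uncertain, -3.58 ± 0.43; Ugt2b1 -1.11 ± 0.21). Female-biased genes had 4 higher and 2 lower of 14, where the largest gain was Cyp2b13, uncertain (29.1 ± 38.3 against 0.0178 ± 0.0308 CPM, mean ± SD), at 73.3 CPM in replicate 3 and 8.39 and 5.71 CPM in the other two 16-week HFD libraries, followed by Cyp2b9 (8.36 ± 0.83). Gluconeogenesis and amino acid catabolism had 5 lower and 2 higher of 16, with Tdo2 at -1.05 ± 0.16 and Got1 at -2.40 ± 0.40. G6pc, the last enzyme of glucose release, was at -1.32 ± 0.37 (adjusted p = 0.0056). The matrix genes Col1a1 (2.65 ± 0.63) and Col3a1 (1.87 ± 0.47) were among 9 higher and 1 lower of 19. Igfbp1, a gene repressed by insulin, was lower (-2.54 ± 0.54, adjusted p = 0.000405). Irs2 (-0.93 ± 0.45, adjusted p = 0.117), Pck1 (-0.32 ± 0.22, adjusted p = 0.276) and Egr1 (0.60 ± 0.71, adjusted p = 0.547) were not called.

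In all, 4539 genes (32.3% of those tested) differed after 16 weeks of HFD, 2250 higher and 2289 lower (3 against 3 libraries). By more than 2-fold, 684 were higher and 326 lower. The counts of list members called stand beside this share of all genes. With the length and GC trends removed 4473 were called, 3410 of them shared with the 4539, and Irs2 passed (-1.14, adjusted p = 0.0427). None of 17 pancreatic acinar genes was called, with a median of -4.14 (camera adjusted p = 0.00432; adjusted p = 0.861 with an estimated correlation), and Ctrb1 was 392, 163 and 61.3 CPM in the chow basal and 0.415, 36.9 and 0.441 CPM in the 16-week HFD basal libraries. Adjusted over the list alone, the counts were 26 higher for interferon, 11 and 3 for fatty acid synthesis, 2 and 16 for oxidation, 11 and 3 for the clock and 12 higher for the unfolded protein response. They were 10 and 1 for acute phase, 1 and 11 for ribosome biogenesis, 2 and 10 for male-biased, 4 and 2 for female-biased, 2 and 6 for gluconeogenesis and 10 and 1 for matrix genes. Camera gave, for the lists in this order, adjusted p = 4.62e-16, 0.00324, 2.02e-05, 0.00383, 0.00103, 0.0104, 0.000897, 0.00229, 0.352, 0.0308 and 0.0502 with the preset correlation of 0.01. With an estimated correlation the same lists had adjusted p = 0.373, 0.373, 0.641, 0.373, 0.861, 0.861, 0.373, 0.744, 0.861, 0.861 and 0.861. The median of the female-biased genes was negative (-0.31) while their mean (1.49) and the camera direction were positive. Without 16-week HFD basal replicate 3, Col1a1 was 1.43 and Col3a1 0.86 and neither passed (adjusted p = 9.92e-05 to 0.0807 and 0.000373 to 0.144 over the alternatives). Without replicate 1 of both 16-week HFD basal and metformin, 5 genes of the unfolded protein response were called, and acute phase genes no longer passed as a list.

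**Figure D2:**
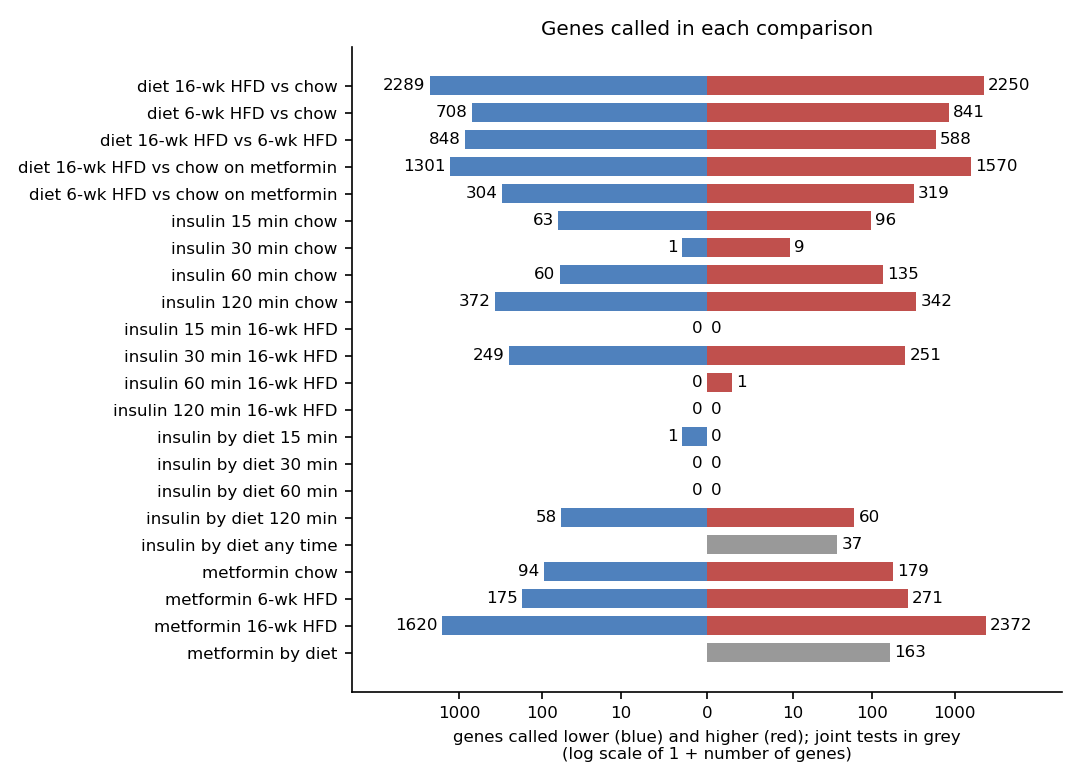
Number of called genes per comparison at a false discovery rate of 0.05, on a log scale of 1 plus the count; red bars are higher genes, blue bars lower genes and grey bars joint tests. The 16-week diet comparison had 4539 calls, and insulin at 15 and 120 min on 16-week HFD had 0.

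After 6 weeks of HFD, the same groups of genes were examined against chow. Interferon-stimulated genes were higher for 24 of 27 (Isg15 2.45 ± 0.30, adjusted p = 1.6e-06; Ifit1 2.40 ± 0.30). Clock genes were higher for 7 of 18 (Bhlhe40 2.10 ± 0.25, adjusted p = 9.84e-07; Per3 1.57 ± 0.38). Fatty acid and triglyceride synthesis had 8 higher and 1 lower of 22 (Mid1ip1, a partner of the acetyl-CoA carboxylases, 1.39 ± 0.21; Srebf1 1.64 ± 0.29). Cholesterol genes were higher for 3 of 23, a share near the 11% of all genes tested that were called. Lower genes were 4 of 16 in gluconeogenesis and amino acid catabolism (Sdsl -1.88 ± 0.32, Got1 -2.33 ± 0.40) and 5 of 24 in ribosome biogenesis (Nop58 -0.63 ± 0.11; Nop56, uncertain, -0.63 ± 0.14). The largest rises were Myh4, a muscle myosin and uncertain (8.43 ± 2.27), and the cytochrome Cyp2b9 (5.58 ± 0.76). The largest falls were E030018B13Rik (-4.78 ± 0.53), which lies within the span of Klf13, and Cyp3a44, uncertain (-3.23 ± 0.52). Igfbp1 was lower (-1.73 ± 0.52, adjusted p = 0.0259), while Irs2 (-0.67 ± 0.44), G6pc (-0.16 ± 0.36), Pck1 (-0.04 ± 0.22) and Egr1 (1.77 ± 0.72) were not called.

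This comparison called 1549 genes, 841 higher and 708 lower (3 against 3 libraries). Pancreatic acinar genes had 0 of 17 called and a median of -4.23 (camera adjusted p = 0.00032; adjusted p = 0.786 with an estimated correlation), with Ctrb1 at 25.5, 7.47 and 0.914 CPM in the 6-week HFD basal libraries. Camera gave adjusted p = 2.29e-31 for interferon, 0.000528 for the clock, 0.00298 for fatty acid synthesis, 0.00274 for cholesterol, 0.00274 for gluconeogenesis and 0.000558 for ribosome biogenesis. Interferon held at adjusted p = 0.033 with an estimated correlation. The others had adjusted p = 0.272, 0.347, 0.937, 0.627 and 0.347 with an estimated correlation. By calls adjusted over the list alone, 25 interferon genes were higher, and 10 clock genes higher and 1 lower. The same test gave 10 of fatty acid synthesis higher and 2 lower, 4 of cholesterol higher, 6 of gluconeogenesis lower and 7 of ribosome biogenesis lower. The count was 778 without chow basal replicate 2, 801 without chow basal replicate 3, 955 without 6-week HFD basal replicate 1 and 989 without replicate 2 of that group. Igfbp1 did not pass without chow basal replicate 3 or 6-week HFD basal replicates 1 or 3 (-1.93 to -1.48, adjusted p = 0.00764 to 0.118 over the alternatives). Myh4 did not pass without chow basal replicates 2 or 3 or 6-week HFD basal replicate 1, where it was 3.35 (adjusted p = 0.00717 to 0.411 over the alternatives).

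Between 16 and 6 weeks of HFD, 1436 genes (10.2% of those tested) differed in basal livers, 588 higher and 848 lower at 16 weeks (3 against 3 libraries of different mice). Fatty acid oxidation and ketogenesis had 10 of 30 genes lower (Cyp4a10, uncertain, -1.30 ± 0.22; Cyp4a14 -1.34 ± 0.25), and male-biased genes 5 of 15 lower (Cyp4a12b, uncertain, -1.92 ± 0.41). Higher genes were 5 of 14 female-biased genes (Hao2, a peroxisomal oxidase, 3.08 ± 0.62), and 7 of 27 genes of xenobiotic metabolism (Cyp2b13, uncertain, 4.39 ± 0.94; Cyp2b9 2.77 ± 0.61). Also higher were 4 of 14 liver endothelium genes (Eng 0.72 ± 0.15), 3 of 25 acute phase genes (Lcn2 3.21 ± 0.82) and 3 of 22 macrophage genes (Cx3cr1, a chemokine receptor, 1.75 ± 0.44). For the acute phase and macrophage lists, the share called was near that of all genes tested. The lipogenic gene Thrsp was also higher at 16 than at 6 weeks (2.72 ± 0.52). The lower genes with the largest folds were muscle genes that were at 0 in all 16-week HFD basal libraries, such as Myh1, uncertain (103.1 ± 144.5 CPM, mean ± SD of the 6-week HFD basal libraries), and Tnnt3 (70.88 ± 101.2 CPM). G6pc was lower (-1.16 ± 0.36, adjusted p = 0.0369). Igfbp1 (-0.81 ± 0.51), Irs2 (-0.26 ± 0.45), Pck1 (-0.28 ± 0.22), Srebf1 (0.53 ± 0.28) and Egr1 (-1.17 ± 0.70) were not called.

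For this comparison camera gave adjusted p = 4.26e-07 for oxidation, 2.91e-05 for male-biased, 0.00788 for female-biased and 0.00203 for xenobiotic genes. It gave 0.000122 for endothelium, 0.000154 for acute phase and 0.00195 for macrophage genes. None held, at adjusted p = 0.587, 0.587, 0.587, 0.75, 0.75, 0.75 and 0.75 with an estimated correlation. In tests adjusted over the list alone, 11 oxidation and 9 male-biased genes were lower, and 5 female-biased, 10 xenobiotic, 8 endothelium, 5 acute phase and 4 macrophage genes were higher. Calls numbered 904 in a fit of only the groups compared and 905 with length and GC trends removed (715 shared with the 1436), 602 without 16-week HFD basal replicate 2, 536 without 6-week HFD basal replicate 1 and 844 without its replicate 2. G6pc was lost with the trends removed, without 6-week HFD basal replicates 1 or 2 or without any 1 of the 16-week HFD basal libraries (adjusted p = 0.0159 to 0.178 over the alternatives). Lcn2, Myh1 and Tnnt3 were lost without 6-week HFD basal replicate 1 (adjusted p = 0.00012 to 0.0519, 9.4e-14 to 0.0873 and 9.74e-22 to 0.094). Cyp2b13 was lost without 16-week HFD basal replicate 3 (0.00121 to 0.0898) and Cx3cr1 without 6-week HFD basal replicate 2 or 16-week HFD basal replicate 3 (0.00467 to 0.15).

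In metformin-treated mice, 16 weeks of HFD against chow called 2871 genes (20.4% of those tested), 1570 higher and 1301 lower (3 against 3 libraries). Higher genes were 19 of 27 interferon-stimulated genes (Isg15 1.94 ± 0.29, adjusted p = 2.42e-05), 18 of 19 genes of the unfolded protein response (Creld2 2.23 ± 0.39; the growth factor Manf 1.63 ± 0.30) and 13 of 32 subunits of complex I (Ndufb3 0.63 ± 0.15). Gluconeogenesis and amino acid catabolism had 6 of 16 lower (Got1 -2.13 ± 0.40, Ppargc1a -1.13 ± 0.24), and FoxO-type fasting targets 7 lower and 1 higher of 16. Srebf1 (1.30 ± 0.29) and Cyp2b9 (6.58 ± 0.76) rose, and Igfbp1 (-1.62 ± 0.52), Irs2 (-1.79 ± 0.49), G6pc (-1.25 ± 0.37) and Pck1 (-0.74 ± 0.22) fell, while Egr1 (1.78 ± 0.72) was not called. With metformin, 6 weeks of HFD called 623 genes, 319 higher and 304 lower (3 against 3 libraries). Higher were 18 of 27 interferon-stimulated genes (Gbp3 2.11 ± 0.34, Ifit1 1.80 ± 0.29) and 4 of 22 genes of fatty acid synthesis (Dgat2 0.74 ± 0.13). There were 4 of 16 of gluconeogenesis lower (Sdsl -1.48 ± 0.33) and 5 lower and 1 higher of 27 xenobiotic genes (Cyp3a11 -2.81 ± 0.47, Cyp2b9 4.65 ± 0.70). Srebf1 was higher (1.25 ± 0.29), and Igfbp1 (-1.64 ± 0.52), Irs2 (-1.10 ± 0.47), G6pc (-1.12 ± 0.36), Pck1 (-0.41 ± 0.22) and Egr1 (0.92 ± 0.71) were not called.

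Camera for the metformin-treated mice gave, at 16 weeks, adjusted p = 2.25e-12 for interferon, 9.44e-11 for the unfolded protein response, 5.77e-06 for complex I, 0.00572 for gluconeogenesis and 0.00909 for FoxO-type targets. None held, with adjusted p = 0.659, 0.659, 0.813, 0.692 and 0.692 with an estimated correlation. At 6 weeks the values were 1.8e-25 for interferon, 0.000209 for fatty acid synthesis, 0.000325 for gluconeogenesis and 0.0285 for xenobiotic genes. These became adjusted p = 0.0872, 0.222, 0.595 and 0.685 with an estimated correlation. For calls adjusted over the list alone, the 16-week counts in this order were 24 higher, 19 higher, 20 higher, 1 higher and 7 lower, and 1 higher and 8 lower. The 6-week counts were 25 higher, 5 higher, 7 lower, and 2 higher and 9 lower. Complex I had 2 higher and 1 lower with the length and GC trends of the libraries removed. The 16-week count was 285 in a fit of only the groups compared, where Creld2, Manf, Ndufb3, Ppargc1a, Igfbp1, Irs2 and Pck1 were lost, and 1677 without replicate 1 of both 16-week HFD basal and metformin. It was 1859 without chow metformin replicate 3 and 1635 without 16-week HFD metformin replicate 1. Without the latter, Ndufb3, Igfbp1, Irs2 and Pck1 did not pass (adjusted p = 0.000486 to 0.17, 0.0148 to 0.266, 0.00259 to 0.131 and 0.00706 to 0.154 over the alternatives). Igfbp1 and Pck1 were also lost without chow metformin replicate 3, Pck1 without replicate 2 of that group, and G6pc without chow metformin replicate 3 or 16-week HFD metformin replicate 2 (0.00543 to 0.0869). Egr1 passed without 16-week HFD metformin replicate 1 (0.0225 to 0.681). At 6 weeks the count was 411 without chow metformin replicate 2, 240 without its replicate 3, 275 without 6-week HFD metformin replicate 1 and 357 without its replicate 2, and Srebf1 was lost without chow metformin replicate 3 or 6-week HFD metformin replicate 2 (0.000558 to 0.092).

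The diet response was compared between mice without and with metformin gene by gene. For 16 weeks of HFD the log2 fold changes had a Pearson correlation of 0.577 and a Spearman correlation of 0.495 over all genes, with 66.3% of genes of the same sign. Among 5839 genes called in either, the correlations were 0.709 and 0.683, and 1542 of the 1571 genes called in both had the same direction (855 higher and 687 lower, against 251.1 and 211.7 by chance). For 6 weeks the correlations were 0.501 and 0.49 over all genes, 0.746 and 0.8 over 1784 genes called in either, and 387 of 388 genes called in both had the same direction (216 higher and 171 lower, against 19.1 and 15.3 by chance).

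**Figure D3:**
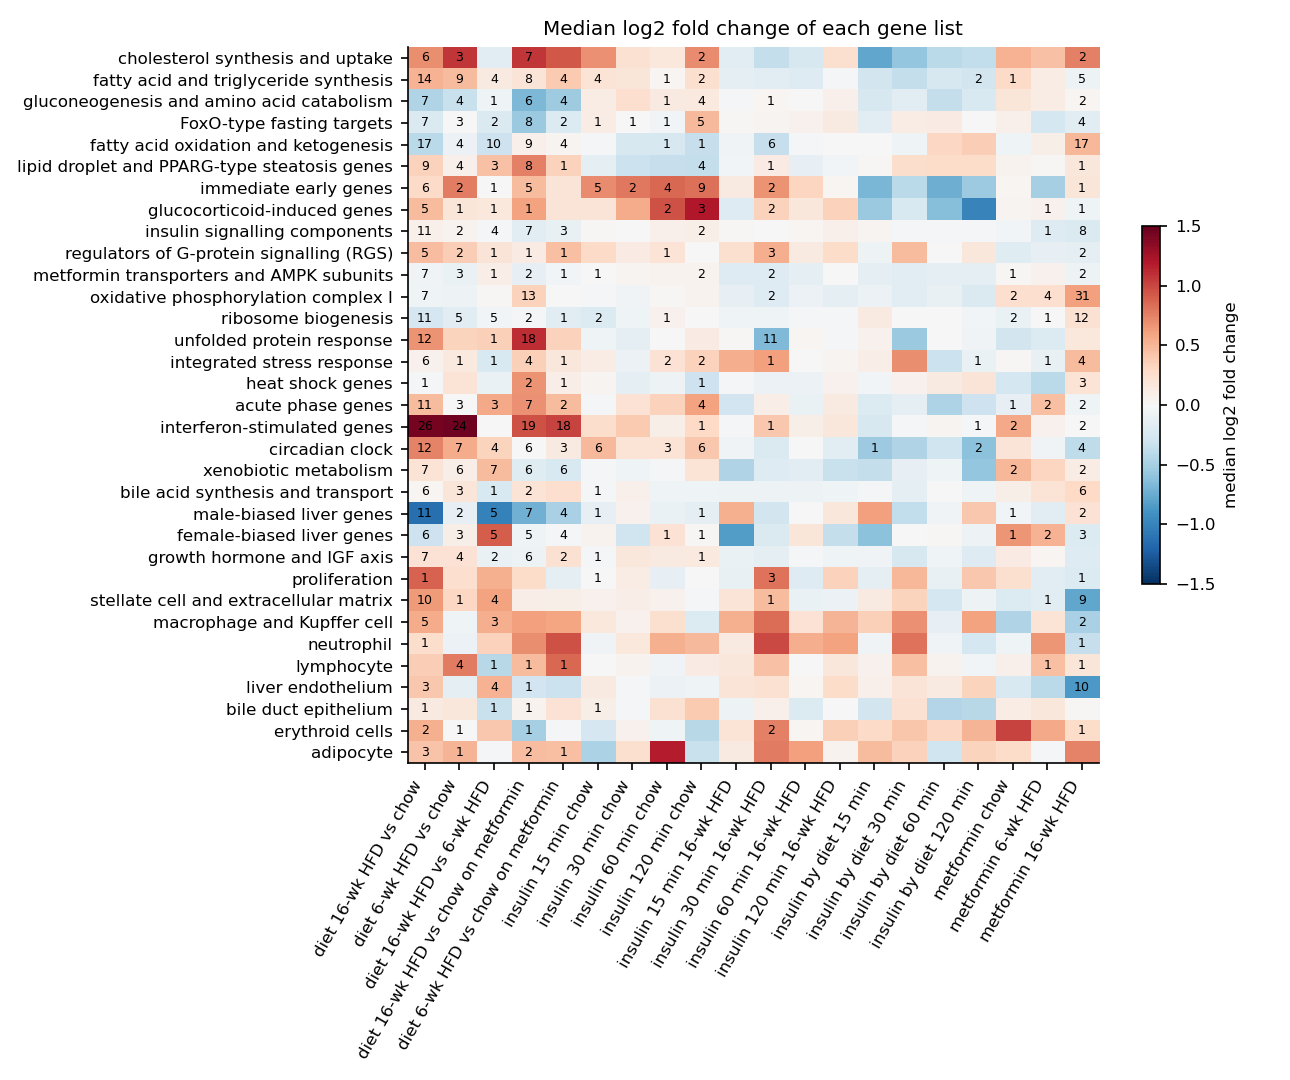
Median log2 fold change of 33 gene lists (vertical, pancreatic acinar genes not drawn) in each comparison (horizontal), red above 0 and blue below; the number in a cell is how many members were called. Interferon-stimulated genes had 26 calls after 16 weeks of HFD, and complex I subunits had 31 calls with metformin on 16-week HFD.

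Insulin in chow mice changed 159 genes at 15 min, 96 higher and 63 lower (3 against 3 libraries). Clock genes were higher for 6 of 18 (the repressor Bhlhe40 2.07 ± 0.25, adjusted p = 9.91e-06; Gm129 2.82 ± 0.55), and immediate early genes for 5 of 25 (Jun 2.23 ± 0.42, adjusted p = 0.00479; Fos 3.06 ± 0.59). Fatty acid and triglyceride synthesis had 4 of 22 higher (Mid1ip1 1.61 ± 0.22, adjusted p = 7.45e-05), and ribosome biogenesis 2 of 24 lower (Nop58 -0.65 ± 0.11). The largest fall was Cyp7a1, the first enzyme of bile acid synthesis (-2.53 ± 0.61, adjusted p = 0.0277). Igfbp1 (-0.12 ± 0.51), Irs2 (-0.21 ± 0.45), G6pc (0.64 ± 0.36), Pck1 (0.42 ± 0.22), Srebf1 (0.42 ± 0.29) and Egr1 (1.84 ± 0.72) were not called. Camera gave adjusted p = 8.31e-08 for the clock, 2.06e-07 for immediate early genes, 0.00239 for fatty acid synthesis and 1.74e-06 for ribosome biogenesis. The clock held at adjusted p = 0.0258 with an estimated correlation, while the others had adjusted p = 0.283, 0.283 and 0.134 with an estimated correlation. When adjusted over the list alone, 8 clock genes were higher and 2 lower, 11 immediate early genes higher, 5 of fatty acid synthesis higher and 1 lower, and 4 of ribosome biogenesis lower. The count was 60, 20 and 82 without chow basal replicates 1, 2 and 3, and 66 and 26 without replicates 2 and 3 at 15 min. Without 15 min replicate 3, Jun (1.54), Fos and Gm129 did not pass (adjusted p = 9.26e-05 to 0.111, 0.000114 to 0.0725 and 4.27e-05 to 0.0917 over the alternatives). Fos and Gm129 were also lost without chow basal replicates 1 and 2 in turn, and Cyp7a1 was lost without chow basal replicates 1 or 2 or any 15 min library (0.00119 to 0.189).

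At 30 min of insulin on chow, 10 genes were called, 9 higher and 1 lower (3 against 3 libraries; 1049 genes at unadjusted p below 0.05). Txnip, which restrains glucose uptake, was lower (-2.30 ± 0.26, adjusted p = 2.81e-06), and the immediate early gene Nr4a1 (3.67 ± 0.68, adjusted p = 0.01), the phosphatase gene Dusp1 (2.52 ± 0.52) and Gm6484 (2.43 ± 0.39) rose. Of 25 immediate early genes, 2 were called, with 13 higher and 1 lower adjusted over the list alone and camera adjusted p = 2.47e-11 (adjusted p = 0.197 with an estimated correlation). Acinar genes had 0 of 17 called and a median of -2.40 (camera adjusted p = 0.00817; adjusted p = 0.895 with an estimated correlation). Igfbp1 (-0.91 ± 0.51), Irs2 (-1.47 ± 0.47), G6pc (-0.29 ± 0.36), Pck1 (0.41 ± 0.22), Srebf1 (0.24 ± 0.29) and Egr1 (0.68 ± 0.71) were not called. The count was 1 and 2 without chow basal replicates 1 and 3 and 4 without 30 min replicate 3, and Nr4a1 did not pass without any of these (adjusted p = 8.4e-06 to 0.183 over the alternatives). Gm6484 was lost without chow basal replicate 1 (5.49e-08 to 0.0738), and Dusp1 without any chow basal library or 30 min replicates 2 or 3 (0.000903 to 0.309).

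By 60 min on chow, 195 genes were called, 135 higher and 60 lower (3 against 3 libraries). Immediate early genes were higher for 4 of 25 (Nr4a1 3.94 ± 0.68, adjusted p = 0.0011) and glucocorticoid-induced genes for 2 of 13 (the kinase gene Sgk1 1.31 ± 0.23, the clock gene Per1 1.23 ± 0.23). Other large rises were Cux2 (3.63 ± 0.84) and the kinase gene Plk3 (3.02 ± 0.45, adjusted p = 0.000342). Angptl4, an inhibitor of lipoprotein lipase, was the 1 lower gene of 30 in fatty acid oxidation and ketogenesis (-1.02 ± 0.16). Txnip was still lower (-1.97 ± 0.26, adjusted p = 8.34e-05), and Bhlhe40 was higher (1.78 ± 0.25) among 3 of 18 clock genes. Igfbp1 (0.14 ± 0.51), Irs2 (-0.56 ± 0.45), G6pc (-0.04 ± 0.36), Pck1 (0.47 ± 0.22), Srebf1 (0.11 ± 0.29) and Egr1 (0.49 ± 0.71) were not called. Camera gave adjusted p = 1.52e-08 for immediate early, 4.12e-06 for glucocorticoid-induced, 6.39e-06 for oxidation and 0.0045 for clock genes. None held, at adjusted p = 0.255, 0.255, 0.582 and 0.43 with an estimated correlation. Counted as adjusted over the list alone, 12, 4 and 3 genes were higher in the immediate early, glucocorticoid and clock lists and 3 lower in oxidation. Calls numbered 97, 53 and 103 without chow basal replicates 1, 2 and 3, and 70 and 93 without 60 min replicates 1 and 3. Cux2 was lost without chow basal replicates 1 or 2 or 60 min replicate 1 (adjusted p = 0.00373 to 0.15 over the alternatives).

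After 120 min on chow, 714 genes were called, 342 higher and 372 lower (3 against 3 libraries). Clock genes were higher for 6 of 18 (Bhlhe40 2.37 ± 0.25, adjusted p = 4.38e-07; Nfil3 1.69 ± 0.31), and immediate early genes were 7 higher and 2 lower of 25 (Btg2 2.67 ± 0.44, Junb 2.49 ± 0.46). Acute phase genes were higher for 4 of 25 (Saa4 1.54 ± 0.29), and the chemokine gene Cxcl1 had the largest rise (4.82 ± 0.80, adjusted p = 0.000323). Lipid droplet genes were lower for 4 of 16 (Plin2, a droplet coat protein, -1.08 ± 0.19), and 1 of 30 oxidation genes was lower. Igfbp1 (1.84 ± 0.52, adjusted p = 0.0306) and Ppargc1a (1.02 ± 0.23) were higher among 4 higher and 1 lower of 16 FoxO-type targets. Irs2 (0.47 ± 0.44), G6pc (0.74 ± 0.36), Pck1 (0.50 ± 0.22), Srebf1 (0.65 ± 0.29) and Egr1 (1.39 ± 0.71) were not called. Camera gave adjusted p = 2.95e-06 for clock, 4.05e-06 for immediate early, 3.58e-06 for acute phase, 0.00395 for lipid droplet, 1.9e-09 for oxidation and 0.0213 for FoxO-type genes. Again none held, at adjusted p = 0.0893, 0.325, 0.527, 0.313, 0.301 and 0.527 with an estimated correlation. In the same order and adjusted over the list alone, the counts were 7 higher, 12 higher and 2 lower, 9 higher, 4 lower, 18 lower, and 6 higher and 2 lower. The count was 467, 306 and 468 without chow basal replicates 1, 2 and 3, and 374 and 275 without 120 min replicates 2 and 3. Igfbp1 was lost without each of these 5 libraries (adjusted p = 0.00605 to 0.173 over the alternatives), and Ppargc1a without 120 min replicate 3 (0.000709 to 0.0603). Cxcl1 was 2.34 without 120 min replicate 2 and did not pass in a fit of only the groups compared (adjusted p = 1.42e-08 to 0.0518 over the alternatives).

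**Figure D4:**
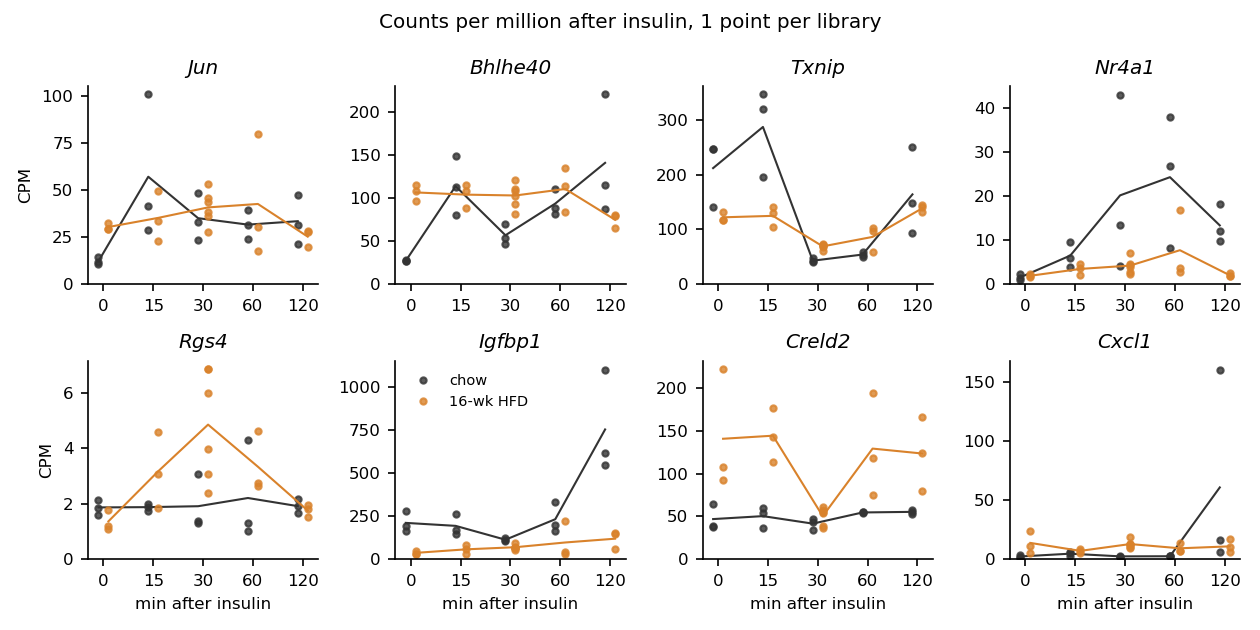
CPM of 8 genes in each library against minutes after insulin (0, 15, 30, 60 and 120, equally spaced), black for chow and orange for 16-week HFD, with lines through group means. Mean Rgs4 was 1.36 at 0 min and 4.86 at 30 min on 16-week HFD.

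On 16-week HFD, insulin called 0 genes at 15 min with edgeR (742 genes at unadjusted p below 0.05; 4 genes with DESeq2) and 0 at 120 min (1176 genes; 8 with DESeq2), 3 against 3 libraries each. At 60 min 1 gene was called, Fam108b (0.73 ± 0.13, adjusted p = 0.0265), which did not pass without 16-week HFD basal replicate 2 or 60 min replicates 1 or 3 (adjusted p = 0.000105 to 0.897 over the alternatives). The count at 60 min was 0 without basal replicate 2 or 60 min replicate 1, 3 without basal replicate 3 and 2 without 60 min replicate 3. At 120 min Igfbp1 (1.71 ± 0.52, adjusted p = 0.38), Egr1 (2.36 ± 0.73, adjusted p = 0.392), G6pc (0.74 ± 0.36), Irs2 (0.59 ± 0.46), Pck1 (0.12 ± 0.22) and Srebf1 (-0.27 ± 0.28) were not called. At 60 min no call was made for Igfbp1 (1.42 ± 0.52), Irs2 (-0.02 ± 0.46), G6pc (0.08 ± 0.36), Pck1 (0.06 ± 0.22), Srebf1 (-0.34 ± 0.28) and Egr1 (0.86 ± 0.70), and Igfbp1 was -0.07 without 60 min replicate 1, which held 221 CPM against 41.7 and 27.2 CPM in the other two. At 15 min the values not called were Igfbp1 (0.65 ± 0.51), Irs2 (0.28 ± 0.46), G6pc (0.30 ± 0.36), Pck1 (0.03 ± 0.22), Srebf1 (0.23 ± 0.28) and Egr1 (0.24 ± 0.70). At 15 min of 17 pancreatic acinar genes 15 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 3.75e-05; adjusted p = 0.82 with an estimated correlation). Ctrb1 was 2.07, 1.26 and 3520 CPM in replicates 1, 2 and 3 at 15 min, the last its highest value in any library. In the 16-week HFD basal libraries it was 0.415, 36.9 and 0.441 CPM. At 120 min these genes had 0 called and a median of 4.06 (camera adjusted p = 0.000102; adjusted p = 0.917 with an estimated correlation).

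At 30 min of insulin on 16-week HFD, with 6 against 3 libraries, 500 genes were called, 251 higher and 249 lower. Genes of the unfolded protein response were lower for 11 of 19 (Creld2 -1.49 ± 0.31, adjusted p = 0.0134; Derl3 -2.39 ± 0.54), and genes of fatty acid oxidation and ketogenesis for 6 of 30 (Cyp4a32, uncertain, -0.70 ± 0.15; Cpt2 -0.37 ± 0.09). Regulators of G-protein signalling were higher for 3 of 12, namely Rgs4 (1.82 ± 0.37, adjusted p = 0.013), Rgs1 (1.97 ± 0.43) and Rgs2 (1.02 ± 0.27). Immediate early genes were higher for 2 of 25 (Klf4 1.44 ± 0.33), and the stress gene Ddit4 had a rise of 1.91 ± 0.39. Igfbp1 (0.93 ± 0.46), Irs2 (-0.59 ± 0.40), G6pc (-0.25 ± 0.31), Pck1 (-0.01 ± 0.19), Srebf1 (0.14 ± 0.24) and Egr1 (1.32 ± 0.64) were not called. Camera gave adjusted p = 4.63e-12 for the unfolded protein response, 2.21e-11 for oxidation, 0.00535 for the RGS genes and 0.000311 for immediate early genes. With an estimated correlation these had adjusted p = 0.484, 0.484, 0.484 and 0.563. Adjusted over the list alone, 18 and 19 genes were lower and 4 and 8 higher in these lists. The count was 28 in a fit of only these groups, 0 with the deposited normalized values, 0 without replicate 1 of both 16-week HFD basal and metformin, 984 with DESeq2, 322 without a filter, 458 with length and GC trends removed (282 shared with the 500), 1744 without replicates 4 to 6 and 1734 with the replicate number as a block. Replicate numbers 4 to 6 occur only in this group, so the block takes up these libraries whole. The block fit of this comparison therefore rests on the same 30 min libraries as the fit without replicates 4 to 6. Calls numbered 0 without 16-week HFD basal replicate 1, 68 without its replicate 2 and 819 without its replicate 3. They numbered 260, 204 and 769 without 30 min replicates 1, 4 and 5. All genes named in this paragraph as called were lost without basal replicate 1, with or without metformin replicate 1, and with the deposited normalized values, and all but Ddit4 and Rgs1 in the fit of only these groups. Adjusted p over the alternatives was 0.00181 to 0.264 for Creld2, 0.00604 to 0.4 for Derl3 and 0.000283 to 0.185 for Ddit4. Rgs1, Cpt2, Cyp4a32 and Klf4 were also lost without basal replicate 2, and Rgs2 without basal replicate 2 or 30 min replicates 1, 2 or 4 (0.000657 to 0.204, 0.00257 to 0.238, 0.00214 to 0.202, 0.0019 to 0.228 and 0.00738 to 0.31).

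Rgs4, which shortens signals of G-protein-coupled receptors, lies on the minus strand of chromosome 1 at 171671608 to 171677773 (mm9). It was a weakly expressed transcript, at 1.87 ± 0.269 CPM (mean ± SD, 3 libraries) in chow basal, 2.37 ± 0.301 in 6-week HFD basal and 1.36 ± 0.371 in 16-week HFD basal livers. On 16-week HFD its level was 3.17 ± 1.37, 4.86 ± 1.97 (6 libraries), 3.34 ± 1.12 and 1.75 ± 0.225 CPM at 15, 30, 60 and 120 min of insulin. The log2 fold changes were 1.21 ± 0.41 (adjusted p = 0.802), 1.82 ± 0.37 (adjusted p = 0.013), 1.28 ± 0.41 (adjusted p = 0.456) and 0.35 ± 0.43 (adjusted p = 0.831). On chow the changes were -0.01 ± 0.41, 0.00 ± 0.41, 0.21 ± 0.41 and 0.02 ± 0.41 at these times (adjusted p = 1, 1, 0.902 and 0.991). The difference between diets was 1.22 ± 0.58, 1.83 ± 0.55, 1.07 ± 0.58 and 0.33 ± 0.60 (adjusted p = 0.792, 0.148, 0.459 and 0.838). For Rgs4, diet (16 weeks -0.46 ± 0.42, adjusted p = 0.432; 6 weeks 0.33 ± 0.40, adjusted p = 0.673; 16 against 6 weeks -0.79 ± 0.41, adjusted p = 0.223) gave no call, nor did 16 weeks (0.36 ± 0.43, adjusted p = 0.593) and 6 weeks (0.48 ± 0.43, adjusted p = 0.611) against chow on metformin. Metformin (chow -0.29 ± 0.43, adjusted p = 0.788; 6-week HFD -0.14 ± 0.40, adjusted p = 0.875; 16-week HFD 0.53 ± 0.43, adjusted p = 0.378) gave none either. The call at 30 min was kept in 14 of 18 alternatives (1.42 to 2.08, adjusted p = 0.000306 to 0.185). Among the 14, the replicate block (1.66) and the fit without replicates 4 to 6 (1.66) rest on the same 30 min libraries. The call was lost without 16-week HFD basal replicate 1 (0.185) and without that library and 16-week HFD metformin replicate 1 (0.0914). It was also lost in a fit of only the groups compared (0.0902) and with the deposited normalized values (0.0948).

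Whether insulin acted differently on the 2 diets was tested as the difference between the responses (16-week HFD minus chow). At 15 min 1 gene was called, Bhlhe40 (-2.10 ± 0.34, adjusted p = 0.00581, with 848 genes at unadjusted p below 0.05). Bhlhe40 was already higher in 16-week HFD basal than in chow basal livers, so its differences between responses go with unequal starting levels. At 30 min 0 genes were called with edgeR (2022 at unadjusted p below 0.05; 111 with DESeq2) and at 60 min 0 (1810; 83 with DESeq2). At 120 min 118 genes were called, 60 with a higher and 58 with a lower response on HFD. Lower responses included Cxcl1 (-5.17 ± 1.04, adjusted p = 0.0113), the stress cytokine gene Gdf15 (-3.31 ± 0.78) and Bhlhe40 (-2.88 ± 0.34, adjusted p = 8.52e-06), which with Gm129 (-3.02 ± 0.73) made 2 of 18 clock genes lower. Higher responses included the homeobox gene Hhex (2.44 ± 0.50), Smad9 (2.39 ± 0.55), the receptor gene Erbb3 (1.79 ± 0.33, adjusted p = 0.0082) and the cholesterol ester hydrolase Nceh1 (1.36 ± 0.23, adjusted p = 0.00355). A joint test over the 4 times called 37 genes (2001 at unadjusted p below 0.05), first Bhlhe40 (adjusted p = 0.00013), then Plekhf1 (0.00184), Hhex (0.00463), Klf10 (0.00651) and Txnip (0.00651). At 15, 30, 60 and 120 min the differences were 0.77 ± 0.72, 1.84 ± 0.69, 1.28 ± 0.72 and -0.13 ± 0.72 for Igfbp1, 0.49 ± 0.64, 0.88 ± 0.61, 0.54 ± 0.64 and 0.11 ± 0.63 for Irs2, and -0.34 ± 0.51, 0.04 ± 0.48, 0.11 ± 0.51 and 0.01 ± 0.51 for G6pc. They were -0.39 ± 0.31, -0.42 ± 0.29, -0.41 ± 0.31 and -0.38 ± 0.31 for Pck1, -0.19 ± 0.40, -0.10 ± 0.38, -0.44 ± 0.40 and -0.92 ± 0.40 for Srebf1, and -1.59 ± 1.00, 0.63 ± 0.93, 0.37 ± 0.99 and 0.96 ± 0.99 for Egr1, and none was called. Without 16-week HFD 60 min replicate 1 the difference for Igfbp1 at 60 min was -0.21. The medians of 17 acinar genes were 6.46, 6.98 and 3.64 at 15, 30 and 120 min with 0 called at each (camera adjusted p = 0.0032, 0.00374 and 0.00541; adjusted p = 0.924, 0.739 and 0.721 with an estimated correlation), and 16 at 30 min were higher adjusted over the list alone. The lists at 15 and 120 min did not pass without replicate 1 of both 16-week HFD basal and metformin.

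For the clock list at 120 min camera gave adjusted p = 2.93e-05 (adjusted p = 0.183 with an estimated correlation), with 6 genes lower adjusted over the list alone. Bhlhe40 at 15 min was lost without chow 15 min replicate 3 or 16-week HFD 15 min replicate 2, where the count was 0 (adjusted p = 5.49e-06 to 0.0647 over the alternatives). It was 2 without 16-week HFD basal replicate 3 and 3 without 15 min replicate 3 of that diet. At 30 min the count was 1 and 37 without chow 30 min replicates 1 and 3 and 59 without 16-week HFD basal replicate 3. At 60 min it was 11 without chow 60 min replicate 2, 6 without 16-week HFD basal replicate 3, and 86 and 3 without 16-week HFD 60 min replicates 1 and 2. At 120 min it was 8 and 67 without chow basal replicates 2 and 3, and 266, 51 and 23 without chow 120 min replicates 1, 2 and 3. It was also 61 and 63 without 16-week HFD basal replicates 1 and 2, and 55 and 45 without 16-week HFD 120 min replicates 1 and 3. For the joint test it was 17 without chow basal replicate 2 and 22 without chow 15 min replicate 2. It was 78, 13 and 14 without chow 120 min replicates 1, 2 and 3, and 20 and 60 without 16-week HFD basal replicates 1 and 3. Further values were 104 without 16-week HFD 60 min replicate 1, and 15, 24 and 13 without 16-week HFD 120 min replicates 1, 2 and 3. Cxcl1 was lost without chow basal replicate 2 or chow 120 min replicate 2 (adjusted p = 0.000281 to 0.123), and Hhex without chow basal replicate 2 (0.00124 to 0.065). Smad9 was lost without chow basal replicate 2, 16-week HFD basal replicate 3, chow 120 min replicates 2 or 3 or 16-week HFD 120 min replicates 1 or 3 (0.00261 to 0.0951). Gdf15 (0.00448 to 0.105) was lost without the same 6 libraries, chow basal replicate 1 or 16-week HFD 120 min replicate 2. Gm129 (0.00604 to 0.144) was lost without chow basal replicates 2 or 3, 16-week HFD basal replicates 1 or 2, chow 120 min replicate 3 or any 16-week HFD 120 min library. With the length and GC trends removed, Gdf15 and Gm129 did not pass.

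Metformin on chow called 273 genes, 179 higher and 94 lower (3 against 3 libraries). Among genes whose libraries did not overlap between the groups, the largest changes included genes with shared reads: E030024N20Rik, which lies inside Gnaq (3.25 ± 0.37, adjusted p = 1.85e-06, uncertain), Cyp3a44 (-3.15 ± 0.54, uncertain) and Mup9 (-3.12 ± 0.57, uncertain). Complex I had 2 of 32 subunits higher (Ndufa1 0.55 ± 0.10, adjusted p = 0.00129), and interferon-stimulated genes 2 of 27 higher (Bst2 0.81 ± 0.18). Cyp1a1, an enzyme induced by aryl hydrocarbons, was higher (6.95 ± 1.09, adjusted p = 0.000248) with Cyp1a2 (2.84 ± 0.56), the 2 calls among 27 xenobiotic genes. Igfbp1 (0.13 ± 0.51), Irs2 (-0.45 ± 0.45), G6pc (0.20 ± 0.36), Pck1 (0.41 ± 0.22), Srebf1 (0.48 ± 0.29) and Egr1 (0.51 ± 0.71) were not called. Acinar genes had 0 of 17 called and a median of -4.76 (camera adjusted p = 5.84e-07; adjusted p = 0.914 with an estimated correlation), with Ctrb1 at 27.2, 2.59 and 0.493 CPM in the chow metformin libraries. Camera gave adjusted p = 2.52e-06 for complex I, 0.000102 for interferon and 0.0124 for xenobiotic genes, and each had adjusted p = 0.914 with an estimated correlation. Complex I did not pass with length and GC trends removed. With p adjusted over the list alone, 6, 3 and 2 genes were higher. The count was 66 and 99 without chow basal replicates 2 and 3, and 133 and 84 without chow metformin replicates 1 and 2. Without chow metformin replicate 2, Cyp1a1 was 0.29 and Cyp1a2 0.24 and neither passed (adjusted p = 2.78e-06 to 0.817 and 1.81e-05 to 0.837 over the alternatives). Cyp1a2 was also lost without chow basal replicate 2, and Bst2 without chow metformin replicate 2 or chow basal replicates 2 or 3 (0.0026 to 0.101).

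Metformin on 6-week HFD called 446 genes, 271 higher and 175 lower (3 against 3 libraries). Complex I had 4 of 32 subunits higher (Ndufa1 0.62 ± 0.10, adjusted p = 0.000205), with 13 higher adjusted over the list alone and camera adjusted p = 1.12e-09 (adjusted p = 0.963 with an estimated correlation). The largest changes included genes with shared reads, such as Mup8 (4.34 ± 1.05, uncertain), E030024N20Rik (3.81 ± 0.38, uncertain) and Mup10 (-2.64 ± 0.49, uncertain), with Gm20594 at -4.08 ± 0.73. Igfbp1 (0.22 ± 0.51), Irs2 (-0.88 ± 0.47), G6pc (-0.76 ± 0.36), Pck1 (0.03 ± 0.22), Srebf1 (0.08 ± 0.28) and Egr1 (-0.34 ± 0.69) were not called. With length and GC trends removed 235 genes were called, 0 complex I subunits were higher and 2 lower, and Ndufa1 did not pass (adjusted p = 4.33e-07 to 0.1 over the alternatives). The count was 137 without 6-week HFD basal replicate 1, and 207, 148 and 246 without 6-week HFD metformin replicates 1, 2 and 3. Mup8 was lost without 6-week HFD basal replicates 1 or 2 or metformin replicate 3 (adjusted p = 0.00107 to 0.108).

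With metformin on 16-week HFD, 3992 genes (28.4% of those tested) were called, 2372 higher and 1620 lower (3 against 3 libraries). Complex I had 31 of 32 subunits higher (Ndufa1 0.85 ± 0.10, adjusted p = 8.01e-07; Ndufb3 0.89 ± 0.15), and fatty acid oxidation and ketogenesis 17 of 30 higher (Acadvl 0.69 ± 0.11). Lower genes were 10 of 14 of liver endothelium (Eng -0.83 ± 0.15, the scavenger receptor Stab1 -0.91 ± 0.17) and 9 of 19 stellate cell and matrix genes (Loxl2, uncertain, -1.03 ± 0.23; Lrat -0.78 ± 0.19). The largest rises were LOC100048884, for which shared words were not counted (5.67 ± 0.91), and E030024N20Rik, uncertain (4.28 ± 0.39), and the largest fall was Gm8909 (-5.06 ± 0.83). Irs2 was lower (-1.31 ± 0.49, adjusted p = 0.0421), and Igfbp1 (1.05 ± 0.52), G6pc (0.27 ± 0.36), Pck1 (-0.01 ± 0.22), Srebf1 (-0.40 ± 0.28) and Egr1 (1.68 ± 0.71) were not called.

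For metformin on 16-week HFD camera gave adjusted p = 6.19e-15 for complex I, 9.75e-07 for oxidation, 3.98e-06 for endothelium and 0.00754 for matrix genes. The values became adjusted p = 0.806, 0.806, 0.806 and 0.971 with an estimated correlation. List by list, adjusted over the list alone, 32 complex I genes were higher, 20 oxidation genes higher and 1 lower, 12 endothelium genes lower and 9 matrix genes lower. With length and GC trends removed, 7 complex I subunits were higher and 1 lower and their median moved from 0.61 to 0.15, and the count was 2201. A fit of only these 6 libraries called 14 genes, and 30 with the replicate number as a block. Of the genes named above as called on 16-week HFD, E030024N20Rik and Gm8909 passed in both of these fits, LOC100048884 in the latter and no other in either. Without 16-week HFD basal replicate 2 the count was 2537, and without 16-week HFD metformin replicate 1 it was 1614. Irs2 was lost without each 16-week HFD basal library and without metformin replicate 1 (adjusted p = 0.022 to 0.378 over the alternatives). Egr1 passed without 16-week HFD basal replicate 2 or metformin replicate 1 (0.03 to 0.733).

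Whether metformin acted differently by diet was tested jointly over the 3 diets, and 163 genes were called (2531 at unadjusted p below 0.05; 358 called with the replicate number as a block). Among the first were Tmed5 (adjusted p = 0.000872), a protein of vesicle traffic, Fchsd2 (0.0022), Gt(ROSA)26Sor (0.00349) and Armc1 (0.00638). For Tmed5 the response on HFD minus that on chow was 0.17 at 6 weeks and 1.35 at 16 weeks, and for Fchsd2 it was -1.08 and -1.40. The count was 30 in a fit of only these groups, 106 without a filter, 678 with DESeq2, 96 with length and GC trends removed and 81 without replicate 1 of both 16-week HFD basal and metformin. It was 39 and 71 without chow basal replicates 2 and 3, and 43, 63 and 324 without chow metformin replicates 1, 2 and 3. It was 255 and 39 without 16-week HFD basal replicates 1 and 2, 101, 583 and 695 without 16-week HFD metformin replicates 1, 2 and 3, and 92 and 248 without 6-week HFD metformin replicates 1 and 3.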

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

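Chosen only after the results were seen were the length and GC correction, the fits without replicate 1 of both 16-week HFD basal and metformin, the splits that keep same-numbered pairs, the tally of splits by kept labels, and the tests of shared reads, of the spread within the 16-week groups, of genes with no shared word after the correction and of the pancreatic genes. Each result here was set apart because a test of the difference between the responses of 2 diets passed. For insulin (16-week HFD minus chow) such tests called 1 gene at 15 min, 118 genes at 120 min and 37 genes over all 4 times, and for metformin over 3 diets they called 163 genes. At 15 min the gene was Bhlhe40 (-2.10). At 120 min the genes named were Hhex (2.44), Smad9 (2.39), Erbb3 (1.79), Rbm12b (1.52, uncertain), Nceh1 (1.36), Cxcl1 (-5.17), Gdf15 (-3.31), Gm129 (-3.02) and Hmox1 (-2.96). Hmox1 was lost without chow 120 min replicate 2, 16-week HFD 120 min replicates 1 or 3, chow basal replicates 1 or 2 or 16-week HFD basal replicate 2 (adjusted p = 0.00741 to 0.254 over the alternatives), and Rbm12b without chow 120 min replicates 2 or 3, 16-week HFD 120 min replicates 1 or 3, chow basal replicate 2 or 16-week HFD basal replicate 2 (0.00448 to 0.121). Over all times the smallest adjusted p were those of Bhlhe40 (0.00013), Plekhf1 (0.00184), Hhex (0.00463), Klf10 (0.00651) and Txnip (0.00651), and for metformin small values were those of Tmed5 (0.000872), Fchsd2 (0.0022), Gt(ROSA)26Sor (0.00349) and Armc1 (0.00638).

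Other splits of the same libraries were fitted for each of these differences. As many genes were called in 14 of 100 splits at 15 min (7 genes in the highest other split), in 7 of 100 at 120 min (215 genes) and in 14 of 100 for metformin by diet (3002 genes), the real split counted. Chance is not excluded for these 3 counts by this measure. The 13 other such splits at 15 min and the 6 at 120 min all kept or exchanged the chow labels as a whole, so each still held the chow response, and the highest of the splits that mixed them called 0. For insulin over all times 2 of 100 splits called 37 or more (129 genes in the highest other), a share under 0.05. These splits mixed all basal and insulin labels within each diet, which also broke up any response common to both diets. They speak against a division in which no label matters, but cannot decide whether the responses differed between diets. For metformin by diet, 10 of the 13 other such splits kept or exchanged the 16-week HFD labels as a whole, and the highest of those that mixed them called 1874 genes, a sign of structure among the libraries. Among 100 splits that parted every same-numbered pair of the 6-week and 16-week HFD libraries, as the real one does, 19 called 163 or more (3286 in the highest other), and 17 of the 18 others kept or exchanged the 16-week HFD labels as a whole (539 in the highest of the rest).

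Metformin called 3992 genes on 16-week HFD, against 446 on 6-week HFD and 273 on chow. The trends with gene length and GC content do not account for the gap as its whole cause, since 2201 and 235 genes were called on 16-week and 6-week HFD with the trends removed. A single library remains a possible cause, which the counts cannot decide. Without 16-week HFD metformin replicate 1 the fit called 1614 genes on 16-week HFD and 1341 on 6-week HFD. That fit had fewer libraries on 16-week than on 6-week HFD. The 6-week HFD libraries were unchanged, yet their count rose from 446, and all groups share the estimate of spread. Leaving out replicate 1 of 16-week HFD basal as well gave a higher count on 16-week HFD. A spread within the 16-week groups that is larger than the shared estimate could also account for the gap. Fits of only the 6 libraries compared called 14 genes on 16-week HFD and 751 on 6-week HFD. A stronger response to metformin on 16-week HFD cannot be told apart from these: the test by diet still called 96 genes with the trends removed and 81 without replicate 1 of both 16-week HFD basal and metformin, but no value separates a response from a single library or a larger spread.

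With metformin 82 genes were called on all 3 diets, and 81 of them had the same direction on each, 65 higher and 16 lower, against 0.716 expected from the call rates. Reads shared between gene copies could account for part: 37% of the 81 genes had 20% or more of their words in other genes, against 6.62% of the other genes (odds ratio 8.29, 95% interval 5.07 to 13.3). The length and GC trends could account for another part, since 35 of the 81 genes were still called the same way with the trends removed. Of 23 genes with no shared word called the same way (0.193 expected), 9 were still called so with the trends removed, against 0.0449 expected. Words shared between the transcripts counted, and the trends as removed, are thus not needed for these 9 calls. Sequence outside those transcripts and genes on the opposite strand were not checked for them. The expected numbers take the 3 comparisons as independent, while the metformin libraries shared the length trend. An effect of metformin cannot be told apart from the trends for the other 14, nor for the 9 from another difference in preparing the metformin libraries, which all had the length trend.

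Pancreatic acinar genes differed over 100-fold between libraries of the same group, and Ctrb1 ranged from 0.415 to 3520 CPM. Pancreatic tissue taken with some livers fits, as the acinar genes moved together: the SD of the log2 ratio of 2 such genes was 0.16 of the SD of their levels, over the 27 of 45 libraries with 20 CPM or more in total over the 14 acinar genes used. No biological explanation was tested, since the libraries of a group share diet and treatment.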

How the results depend on the processing

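The length and GC correction, the fits without replicate 1 of both 16-week HFD basal and metformin and the combinations with the replicate block were chosen after the results were seen, as were the block for the gene lists and the block and left-out libraries for the correlation of diet responses. Of the counts of called genes under alternatives, 206 stayed within 1.5 times and 156 moved further; list tests with the preset correlation kept their side of the threshold 244 times, lost the call 75 times and gained one 4 times; named genes kept it 3928 times, lost the call 223 times, gained one 20 times and reversed 1 time. The reversal was Cyp1a1 after 6 weeks of HFD with metformin (-5.74), which was 0.92 without chow metformin replicate 2, the library that held the high values; leaving out each library gave -6.32 to 0.92. With RLE scaling no median fold moved by 0.05. Unless a library or fewer tested genes explain a change below, the cause was not tested. Comparisons are named by group; "by diet" is the difference of responses, in the order 15, 30, 60 and 120 min and all times.

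With DESeq2, insulin on chow called 253, 63 and 300 genes at 15, 30 and 60 min, on 16-week HFD 4, 984, 21 and 8 at the 4 times, and by diet 12, 111, 83, 316 and 343; metformin called 472 on chow, 693 on 6-week HFD and 678 by diet. With the deposited normalized values, insulin called 17 genes at 30 min on chow and 0 at 30 and 0 at 60 min on 16-week HFD. Without a filter, 322 genes were called at 30 min on 16-week HFD and 106 for metformin by diet. In fits of only the groups compared, calls were 904 for 16 against 6 weeks, 285 for 16 weeks against chow on metformin, 61 at 30 min on chow, 28 at 30 and 0 at 60 min on 16-week HFD, 8, 7, 3, 217 and 65 for insulin by diet, and for metformin 518 on chow, 751 on 6-week HFD, 14 on 16-week HFD and 30 by diet. With the trends removed, they were 905 for 16 against 6 weeks, 27 at 30 min on chow, 0 at 60 min on 16-week HFD, 3 at 15 min by diet, 63 over all times by diet, and for metformin 235 on 6-week HFD, 2201 on 16-week HFD and 96 by diet. Without replicate 1 of both 16-week HFD basal and metformin, they were 1677 for 16 weeks against chow on metformin, 0 at 30 and 0 at 60 min on 16-week HFD, 78 for all times by diet, and for metformin 2117 on 16-week HFD and 81 by diet. Without replicates 4 to 6 at 30 min, calls were 1744 at 30 min on 16-week HFD, 35 at 30 min by diet and 224 for all times by diet. With an estimated correlation, 2 of 173 list calls held. Over genes of at least 5 CPM, the correlation of 16-week diet responses without and with metformin was 0.703 against 0.577.

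With the replicate block, calls were 27 at 30 min on chow, 1734 at 30 min on 16-week HFD, 4, 24 and 8 at 15, 30 and 60 min by diet, 184 for all times by diet and 358 for metformin by diet; no other count moved by 1.5 times. At 30 min on 16-week HFD, and by diet at 30 min and over all times, the block sets aside libraries whose number occurs in no other group. For metformin, the paired fit of only the groups compared called 815 on 6-week HFD and 30 on 16-week HFD, and the block with trends removed 239 and 2334. Of 273 same-numbered pairs, 73 had correlated deviations over 0.1 and 74 under -0.1.

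Each library of the groups compared was left out in turn. This gave 3436 to 4130 calls for 16 weeks against chow, 778 to 1304 for 6 weeks and 536 to 1127 for 16 against 6 weeks. On metformin it gave 1635 to 3737 and 240 to 578. For insulin on chow it gave 20 to 127, 1 to 14, 53 to 247 and 275 to 829; on 16-week HFD 0 to 0, 0 to 819, 0 to 3 and 0 to 0; by diet 0 to 3, 0 to 59, 0 to 86, 8 to 266 and 13 to 104. For metformin it gave 66 to 347 on chow, 137 to 409 on 6-week HFD, 1614 to 4567 on 16-week HFD and 39 to 695 by diet. For the correlation of diet responses it gave 0.444 to 0.576. These ranges do not cover libraries of other groups, which share the estimate of spread. Without 16-week HFD metformin replicate 1, metformin on 6-week HFD called 1341 genes.

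For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split had the most calls in all but insulin at 15 and 120 min on 16-week HFD (0 genes, so 10 of 10 splits reach it; 0 and 1 in the highest other). The highest other split called 0 for 16 weeks, 151 for 6 weeks, 126 for 16 against 6 weeks, 254 and 4 for the diets on metformin, 0 at each time on chow, 0 at 60 min on 16-week HFD, and 1, 100 and 1739 for metformin on chow, 6-week and 16-week HFD (1 of 10 splits each). The splits with 100 and 1739 parted 1 same-numbered pair. Among the 4 splits that part all 3 pairs, as the real one does, the highest other called 1 and 8. These pairs came from a search of the same data, so the smaller set of splits lends neither count independent support. At 30 min on 16-week HFD, 3 of 84 splits called 500 or more, and the highest other, 2125, follows replicates 1 to 3 against 4 to 6, so the larger counts reflect structure of the samples. By diet at 30 and 60 min, with 0 calls, all 100 of 100 splits reached the count (4 and 276 in the highest other). Depth was 35.1 to 50.3 M in 6-week HFD basal and 19.2 to 23.7 M in 6-week HFD metformin libraries. It was 19 to 45.7 M in chow basal and 21 to 23.9 M in 16-week HFD basal libraries. Comparisons with 6-week HFD basal thus set libraries of mostly unlike depth against each other. Weakly expressed genes such as Rgs4 (1.36 CPM in 16-week HFD basal) were counted on few reads.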

Other observations

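Skeletal muscle genes differed widely between libraries of the same group. Myh1 was 268, 40.2 and 0.589 CPM in 6-week HFD basal replicates 1, 2 and 3, where Tnnt3 was 187, 25.3 and 0.467 CPM and Ttn 272, 42.2 and 0.589 CPM. Mean Myh1 (uncertain) was 103.1 ± 144.5 CPM (mean ± SD) in 6-week HFD basal, 21.75 ± 37.67 CPM at 60 min of insulin on 16-week HFD and 12.74 ± 21.93 CPM in chow basal livers, and 0 in 16-week HFD basal livers. Tnnt3 was 70.88 ± 101.2, 20.42 ± 35.33, 6.639 ± 11.22 and 0 CPM in the same groups, and Ttn 105 ± 146.2, 13.87 ± 23.74, 7.569 ± 12.6 and 0.2274 ± 0.04039 CPM.

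Cyp1a1 was 110 ± 188.6 CPM and Cyp1a2 1607 ± 2324 CPM in chow metformin livers, where replicate 2 held the high values, against 0.9016 ± 0.1102 and 224.8 ± 44.26 CPM in chow basal livers. In 6-week and 16-week HFD metformin livers Cyp1a1 was 2.08 ± 0.8684 and 1.155 ± 0.1908 CPM.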
